A study of Homo sapiens with 23 samples.

How the data were processed

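Loops were measured by HiChIP with an antibody against the progesterone receptor in T47D cells, in 1 library labelled T0 and 1 labelled T30, per the labels. Each file lists loops that passed a q-value of 0.05, with near contacts merged, as the deposited files' names and values show. The submitters' processing notes name Bowtie and the builds hg38 and GRCh38, with no role or version; other tools, the settings of the loop calling and the pooling of replicates are not given in the sources used here. Contacts are deposited whole-number counts of read pairs between 2 bins of 5 kb, not normalized, per the file headers and values. The p-value and q-value of each loop come from the authors' bias-corrected model, per the file headers. The authors also give a fraction for each cluster of contacts, which entered no result. Other deposited columns hold the positions of the bins and of the cluster at each end. Every column of the lists that holds sample values was mapped to its sample.

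Gene positions came from a RefSeq gene table of GRCh38.p14, the build of the coordinates, and all 176 distinct genes of the 9 lists were found among 19974 protein-coding genes. The table gives no strand, so start sites could not be placed. The plan called for promoters; a gene was instead counted at a loop when a loop's bin overlapped the gene, and bins that hold either end of the gene were an alternative. Motifs were not searched and scaling by coverage of the ends was not run, because no genome sequence and no coverage were used here.

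Partners are the distinct bins joined to a gene's bins. Each list's count and its summed change in partners (T30 minus T0) were placed among 10000 random lists of the same size, matched on protein-coding genes within 250 kb and on gene length in 5 classes each. Matching on length and the percentile of the summed change were added after the files were seen; the plan placed the count of genes. Percentiles describe these libraries and are not p-values.

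Loops were called shared when the cluster ranges of both ends overlapped by at least 1 bp. This reading of the planned rule was chosen after the overlap under several definitions had been seen, since bins on a fixed grid overlap only where they are identical. Chance overlap came from 1000 random moves of each loop along its chromosome, and random annotation from 200 moves. Contacts of matched loops were compared by an exact two-sided binomial test against the median ratio, with Benjamini-Hochberg adjustment at 0.05. Expected contacts are the Poisson mean whose upper tail at the observed count equals the deposited p-value; that the authors' p is such a tail is an assumption. Intervals are exact binomial intervals at 95%, and those of medians come from resampled loops. Those of a gene's change in partners are normal approximations from the square root of its summed partners. The latter treat partner bins as independent counts, although such bins may share a loop end. Intervals on shares and ratios of loops treat loops as independent, although loops may share an end, so they may be too narrow. All intervals cover counting error only, and read pairs need not be independent molecules.

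The text names the 10 loops with most contacts and the 10 bins with most partners per library, the 10 genes with the largest change of partners in each direction, members of the fixed lists, and the 5 called shared loops with the largest and smallest ratio; no called loop was lower. Of these, the text gives a part where there are many. The lists, this rule, the design of the comparisons and a set of other settings were fixed before the data were examined, with the departures named above. These settings were q under 0.01, at least 10 contacts, lists of equal length, other overlaps, other scalings and other gene definitions. Added after the data were seen were a span of at least 20 kb, gene ends, genes widened by 10 kb, moves within 1 Mb, lists matched on loops within 2.5 Mb, and scaling by expected contacts.

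The steps were tested on simulated data. Of 1329 simulated shared loops, 50 made 2-fold higher gave 17 calls, 50 made 3-fold higher gave 44, 50 made 2-fold lower gave 4 and 50 made 3-fold lower gave 17, with 3 calls among 1129 unchanged loops. All 300 shared loops placed in 1000 were found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.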

Results

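The data were 2 lists of chromatin loops from T47D cells, an established human breast cancer line that expresses the progesterone receptor and responds to progestins. HiChIP joins DNA ends that lie close together in the nucleus and enriches the joined fragments with an antibody, here against the progesterone receptor per the labels. Listed loops and their contacts therefore reflect contact and enrichment together, which were not separated here. The library labelled T0 and the library labelled T30 were 1 sample each. The T30 title reads PR5020, taken here to stand for the receptor and R5020, the synthetic progestin named in the treatment protocol; the labels state neither the unit of the time nor the dose for these libraries. With 1 list per condition, every difference below has no replicate check, and intervals cover counting error only. The T0 list held 7075 loops with 127457 contacts and the T30 list 9591 loops with 135538 contacts. These totals cover listed loops alone, and the sequencing depth of either library is unknown. At the common q-value of 0.05, the largest p-value listed from the authors' model was 0.000233 in T0 and 2.84e-05 in T30. At the 608 pairs of identical bins, the median ratio of T30 to T0 expected contacts was 0.437. The lists were thus not cut at equal p-values or at equal expected contacts. The other samples among the 23 of the series were not analysed here.

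The first comparison asked whether genes known to respond to progestins lay at listed loops before and after exposure. Of 32 progestin target genes fixed in advance, 12 had a loop end in the gene in T0 and 24 in T30, 10 of them in both libraries. Matched random lists averaged 6.01 and 6.76 genes. The list's count lay at the 99.33rd percentile in T0 and the 100th in T30, so it stood high in T0 as well. FKBP5, a co-chaperone of steroid receptors, had 5 loops in T0 and 16 in T30, with 96 and 366 contacts. ZBTB16, a zinc finger transcription factor, had 0 and 13 loops, EGFR, a growth factor receptor, 0 and 4, and S100P, a calcium-binding protein gene, 0 and 4. GREB1, a hormone-responsive growth regulator, had 2 and 6. Against these, BCL6, a transcriptional repressor, had 17 loops in T0 and 12 in T30, ELF5, a transcription factor of the mammary alveolar lineage, had 6 and 2, and SGK1, a kinase, had 2 and 0. EGFR lies in a window of 5 Mb (chromosome 7, 55000001 to 60000000) where T0 listed 0 loops and T30 listed 7. SNAI2, a list member with 0 and 2 loops, lies in one with 0 and 8 (chromosome 8, 45000001 to 50000000). Their 0 in T0 was thus not particular to the gene, and both are among the members with more partners in T30.

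By partner bins, 18 of the 32 genes had more distinct partners in T30, 5 had fewer and 9 had equal numbers, and the list's sum went from 38 to 87. That change of 49 lay at the 99.97th percentile of 10000 random lists matched on gene density and length. The result depended on where a gene was taken to end. With genes widened by 10 kb, a choice made after the data were seen, 19 members had a loop in T0 and 24 in T30, the summed change was 23, and its percentile was 96.5. At the widened genes FKBP5 had 7 loops in T0 and 16 in T30, and ZBTB16 had 7 and 14. Without FKBP5 and ZBTB16 the change at unwidened genes was 21, at the 97.93rd percentile.

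**Figure D1:**
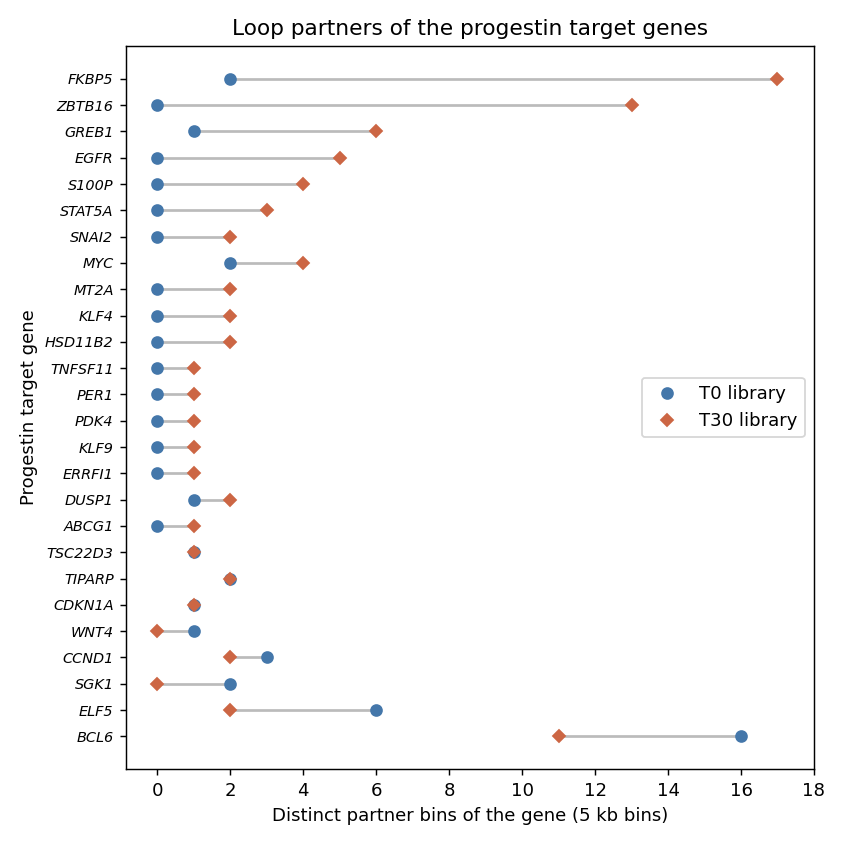
Distinct partner bins (x axis, 5 kb bins) of each progestin target gene with a loop in either library (y axis), with circles for T0 and diamonds for T30. FKBP5 moves from 2 to 17 and ZBTB16 from 0 to 13, while BCL6 moves from 16 to 11; loop ends just outside the gene are not counted.

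At FKBP5 on chromosome 6 (35573590 to 35728583, hg38), the 2 libraries differed in where the loops met. In T30, 16 loops shared the bin from 35725001 to 35730000, which holds the upper end of the gene, and no T0 loop was listed at that bin. The T0 loops instead met in the next bins, at 35730001 and 35735001. Over the region from 35400001 to 35900000 the lists held 7 loops in T0 and 17 in T30. The loop with the most contacts in the gene had 33 in T0, between the bins at 35580001 and 35735001, and 47 in T30, between those at 35685001 and 35725001.

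**Figure D2:**
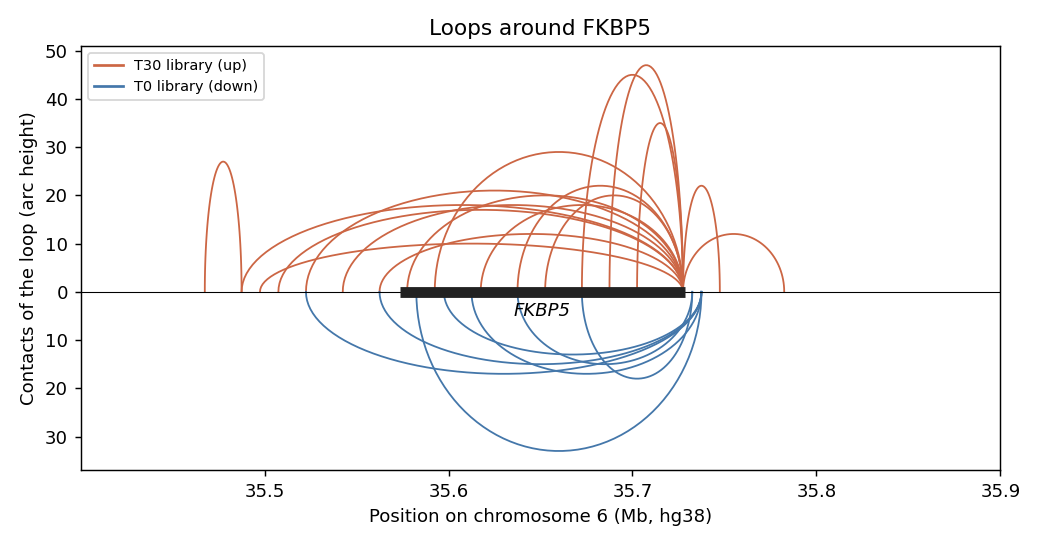
Loops around FKBP5 (black bar) on chromosome 6 (x axis, Mb, hg38), drawn as arcs whose height is the loop's contacts (y axis), T30 upward and T0 downward. The 7 T0 loops meet at bins from 35730001 on, and 16 of the 17 T30 loops meet at the bin from 35725001.

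Genes of luminal breast identity were well covered in both libraries, with 16 of 22 at a loop in T0 and 15 in T30, where random lists averaged 4.12 and 4.67, or 6.28 and 7.52 when matched on loops within 2.5 Mb. GATA3, a luminal transcription factor, had 6 and 7 loops, and its strongest loop in T30, of 19 contacts, spanned 1155 kb. FOXA1, a pioneer factor, had 1 and 4 loops, and GRHL2, an epithelial transcription factor, had 7 and 18. KRT8, a luminal keratin, had 4 and 3 (7 and 4 when widened by 10 kb), CDH1, the epithelial cadherin, 3 and 1, and EPCAM, an epithelial adhesion molecule, 2 and 0. The list's summed change in partners of 4 lay at the 65.99th percentile of random lists. Without GRHL2 it was -4, at the 10.94th percentile. Other forms of the change disagreed: 11 in loops (94.44th percentile) and -18 in contacts (46.05th) at unwidened genes, and 10 in loops (88.17th) and -281 in contacts (2.17th) at genes widened by 10 kb. ESR1 and PGR, which encode the estrogen and progesterone receptors, had no listed loop in either library.

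Estrogen response genes had a loop at 10 of 23 members in T0 and 13 in T30, with a summed change of 11 at the 91.85th percentile. Growth factor and kinase genes had 13 of 20 in each library, 10 of them in both, with the change at the 79.7th percentile. By the count of members with a loop, estrogen genes lay at the 99.87th percentile in T0 and the 100th in T30. Growth factor genes lay at the 100th in each, and cell cycle genes at the 99.9th in T0 and the 87.44th in T30. Cell cycle genes had 9 of 20 in T0 and 6 in T30, at the 17.18th percentile for the change; MYC, a proto-oncogene in 3 of the lists, had 2 loops in T0 and 4 in T30, and 5 in both when widened by 10 kb. Basal and mesenchymal genes had 6 and 8 of 20 (change at the 84.45th percentile), coregulator and chromatin genes 5 and 6 of 20 (65.64th), and housekeeping genes 5 and 6 of 16 (89.94th). When widened by 10 kb, housekeeping genes had 9 in T0 and 6 in T30, with a change in partners of -2 at the 20.43rd percentile. Count percentiles in T0 and T30 were 91.99 and 98.62 for basal, 39.03 and 32.07 for coregulator, and 95.56 and 96.69 for housekeeping genes. Genes of other tissues, the background for the lists, had a loop at 3 of 20 members in each library, 2 of them in both. Their count lay at the 41.99th percentile in T0 and the 25.3rd in T30. Their change in partners of -5 lay at the 4.46th, and PECAM1 alone went from 6 partners to 1. The lists share members, EGFR, CCND1 and MYC among them, and are not independent of each other.

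**Figure D3:**
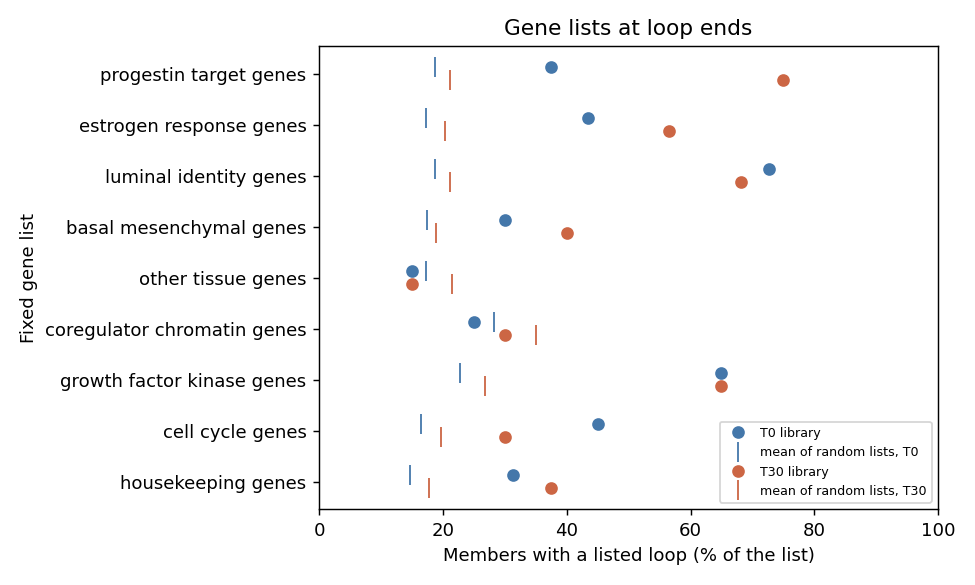
Percent of each fixed list's genes with a listed loop (x axis) for the 9 lists (y axis), with points for T0 and T30 and ticks for the mean of 10000 matched random lists. Progestin target genes stand at 37.5% in T0 and 75% in T30, and luminal identity genes at 72.73% and 68.18%.

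Over all genes, 3938 of 19974 protein-coding genes had a loop end in T0 and 4694 in T30, 2290 of them in both. The largest differences towards T30 in distinct partners were at GSE1, a corepressor subunit gene (53 partners in T0 and 86 in T30), and VAV2, a guanine nucleotide exchange factor (3 and 28). Next came KCNMA1, a potassium channel gene (15 and 39), ZNF704 (1 and 20), ANKRD11, a chromatin regulator (4 and 22), and LOC128462377, which lies within ANKRD11 (3 and 21). KRT37, a hair keratin gene (1 and 19), NDUFAF6, a mitochondrial assembly factor (5 and 23), GTF2IRD1, a transcription factor (0 and 16), and FKBP5 (2 and 17) completed the 10. Part of the KCNMA1 difference came from a T0 hub just outside the gene, since with genes widened by 2500 bp it was 14 in place of 24. The same holds for FKBP5, whose difference with genes widened by 10 kb was 8 in place of 15 (95% counting interval -1.994 to 17.99). At q under 0.01 the VAV2 difference was 14 in place of 25. At the bins that hold a gene end, a setting added after the data were seen, KRT37 (1 partner in T0 and 19 in T30) and FKBP5 (0 and 16) kept a difference of that size, although these bins leave out the T0 hub beside FKBP5. There GTF2IRD1 had 0 and 5, VAV2 2 and 5, KCNMA1 2 and 4, ZNF704 0 and 1, ANKRD11 1 and 1, LOC128462377 none in either, NDUFAF6 1 and 0, and GSE1 8 and 1.

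The largest differences towards T0 were smaller. TPRG1 had 16 partners in T0 and 4 in T30, GPHN, a synaptic scaffold gene, 17 and 6, HDAC9, a histone deacetylase, 11 and 0, SLC35F3 12 and 2, and CAMK1D, a kinase, 12 and 3. SNRPE, a spliceosome component, had 12 and 4, HOXB3, a homeobox gene, 14 and 6, ABCC1, a drug efflux transporter, 8 and 0, ABTB3 8 and 0, and P3H2, a collagen-modifying enzyme, 12 and 4. At bins that hold a gene end, SNRPE (12 and 4) and HOXB3 (8 and 1) kept such a difference, GPHN had 1 and 0, and the other genes of this group had none in either library. At HOXB3 the counting interval of the change included 0. Several of these genes are long, as with GPHN at 1227209 bp and HDAC9 at 915592 bp.

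Contacts of loops found in both libraries were compared next, over 1329 matched pairs. Of these, 608 had both bins identical in the 2 libraries, and the others were matched by overlapping ranges. Relative to the median T30 to T0 ratio of 0.657, 21 loops were higher in T30 and 0 were lower in an exact two-sided binomial test per loop with Benjamini-Hochberg adjustment, which compares 2 libraries and not 2 conditions. At an unadjusted p under 0.05 the numbers were 78 higher and 21 lower. The largest was on chromosome 17, with 10 contacts in T0, between the bins at 40905001 and 41415001, and 44 in T30, between those at 40910001 and 41420001 (scaled log2 ratio 2.74, 95% interval 1.73 to 3.90; exact binomial adjusted p = 1.43e-07). Its T30 end lies in KRT37 and its T0 end just outside. A loop within ARSG, a sulfatase gene, had 16 and 59 contacts (2.49), and loops within CUEDC1 had 23 and 80 (2.40) and 28 and 82 (2.16). The fifth named loop, on chromosome 17 from 40900001 to 41335001 in T0 and from 40910001 to 41340001 in T30, had 10 and 29 contacts (2.14).

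The direction of the calls rested on the scaling. With the ratio of summed contacts (1.06) the same test called 7 loops higher and 123 lower, with no scaling 6 higher and 43 lower, and with each loop's expected contacts 147 higher and 0 lower. Higher in T30 under every one of these scalings were 6 of the 21 loops, none of them with both bins identical in the 2 libraries. They were the loop of 10 and 44 contacts, the ARSG loop, the first and second CUEDC1 loops, a loop from the bin at 35670001 in FKBP5 (18 and 45 contacts) and a loop from 116270001 in MED13L, a Mediator subunit gene (16 and 41). Loops that reached CCND1, the cyclin D1 gene, from 69105001 on chromosome 11 (16 and 32 contacts) were called with the median ratio and with no other scaling. Each called loop with identical bins was missed under some scaling. In simulated counts the test found 17 of 50 loops made 2-fold higher but 4 of 50 made 2-fold lower, so it saw falls less well, and a loop that fell below the authors' threshold in T30 left the comparison.

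**Figure D4:**
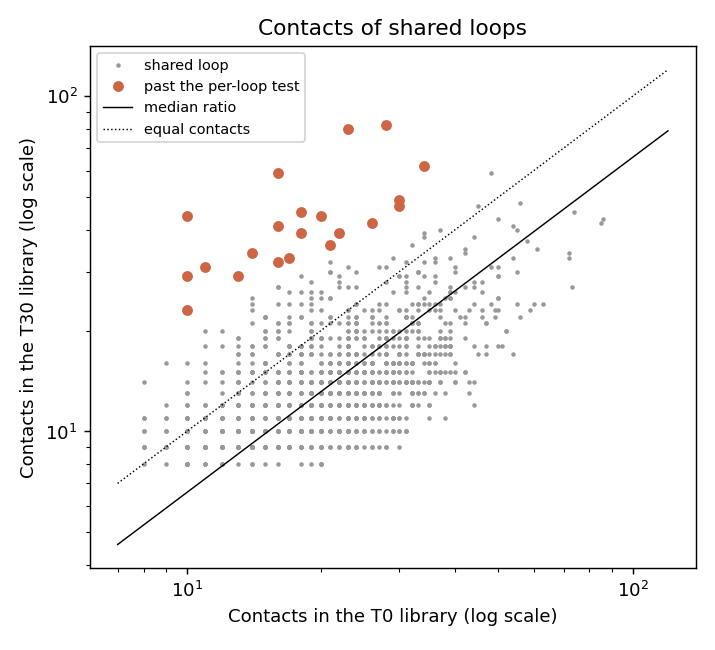
Contacts of the 1329 shared loops in T0 (x axis, log scale) and T30 (y axis, log scale), each point a loop, with the 21 called loops in colour. The solid line is the median ratio of 0.657 and the dotted line marks equal contacts; most loops lie below the dotted line.

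The overlap of the lists asked how far loops present before exposure were listed again. Both ends overlapped a loop of the other list for 1570 of the 7075 T0 loops, or 22.19% (exact 95% interval 21.23 to 23.18), and for 1573 of the 9591 T30 loops, or 16.4% (15.66 to 17.16). Loops moved at random along their chromosome overlapped for 0.115% and 0.106%, and loops moved within 1 Mb for 0.619% and 0.591%. The share depended on the definition: 8.59% of T0 loops had both bins identical in T30, and 36.37% had both within 10 kb. It also depended on span, in opposite directions. At 20 to 50 kb, 38.33% of T0 loops and 5.39% of T30 loops were shared, and at 1000 to 2000 kb 10.97% and 37.5%.

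Spans differed between the lists. The median was 190 kb in T0 and 80 kb in T30. Loops of 20 to 50 kb numbered 360 in T0 and 3024 in T30, and loops of 500 to 1000 kb numbered 743 and 273. T0 also held 574 loops under 20 kb and T30 held none, so the lists differ in their minimum span; with both held to 20 kb or more, the T0 median was 210 kb. T30 had 1.36 loops per T0 loop (exact 95% interval 1.31 to 1.40), and 1.48 at 20 kb or more.

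**Figure D5:**
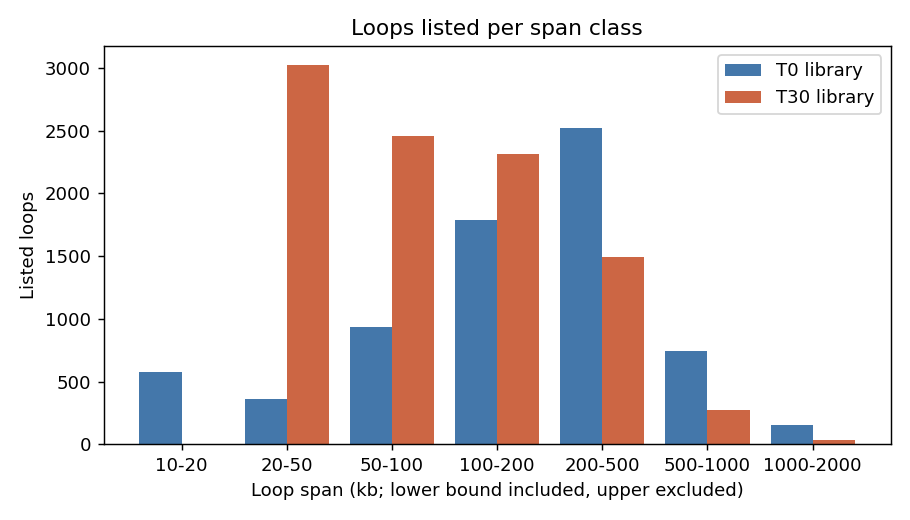
Number of listed loops (y axis) in each span class (x axis, kb) for T0 and T30. From 20 to 50 kb T30 lists 3024 loops against 360 in T0, and from 200 to 500 kb 1491 against 2523.

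Loops were unevenly spread over the genome in both libraries. Chromosome 17 held 8.49 loops per Mb in T0 and 11.1 in T30, chromosome 3 held 4.39 and 5.94, and chromosome 2 held 0.475 and 0.748. T30 had 2.54 loops per T0 loop on chromosome 9, and 0.821 on chromosome 13. Among windows of 5 Mb, the one from 85000001 to 90000000 on chromosome 16, which holds GSE1 and ANKRD11, had 133 loops in T0 and 309 in T30. The window at the start of chromosome 7 had 20 and 140. In the window from 50000001 to 55000000 on chromosome 12, which holds KRT8 and KRT18, the numbers were 121 and 87.

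The bins with the most partners also differed. In T0 the first was the GSE1 bin at 85415001 on chromosome 16, with 21 partners and 24 in T30, and 6 of the first 10 lay on chromosome 3, such as the bin at 194315001 near CPN2 (15 partners in T0 and 5 in T30). In T30, GSE1 held 4 of the first 10 bins, and the KCNMA1 bin at 77430001 had 23 partners against 1 in T0. The bin at 40910001 on chromosome 17 near KRT23 had 20 against 2, the KRT37 bin 19 against 1, the bin at 116390001 on chromosome 12 near MED13L 17 against 5, and the NDUFAF6 bin at 95110001 on chromosome 8 17 against 3. A shift of a hub by a bin counts as a difference in these numbers. The strongest loops of T0 were mostly of 10 kb on chromosome 3, led by 127 contacts between 196150001 and 196160001, a span that the T30 list does not hold. The strongest of T30 lay within GSE1 (89 contacts, 85350001 to 85380001) and CUEDC1 (82 contacts), followed by MYOF (67), ABCC5 (64), KCNMA1 (61), ARSG (59) and BMPER (59).

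Loop ends were placed on protein-coding genes to ask what the loops joined. Both ends lay in genes for 35.82% of T0 loops (exact 95% interval 34.7 to 36.95) and 43.37% of T30 loops (42.38 to 44.37), where loops moved at random gave 31.84% and 34.56%. Neither end did for 19.76% and 20.67%. With bins that hold either end of a gene in place of the whole gene, both ends qualified for 4.96% of T0 loops and 4.71% of T30 loops, with overlapping intervals (4.47 to 5.49 and 4.30 to 5.16).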

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

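Tests chosen only after the result was seen were those of the summed change among matched and region-matched lists and without FKBP5 or FKBP5 and ZBTB16, of the change in contacts, of the minimum span, of depth and of expected contacts. Those at q under 0.01, at 100 to 200 kb, at gene ends and of loops at widened genes were written before their outcome was known. No group held enough samples to look for outlying libraries. Loops outside the assembled chromosomes, which entered no comparison of genes, were listed 4 times in T30 and 0 times in T0.

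Progestin target genes had more partners in T30. An equal gain at all genes would not single out the list, whose change lay at the 99.97th percentile of matched lists. A gain in proportion to T0 loops stays open, since the random lists were not matched on these and the list's T0 count lay at the 99.33rd percentile. Its partners went from 38 to 87, and its loops at genes widened by 10 kb from 76 to 97, where T30 had 1.36 loops per T0 loop. FKBP5 alone did not carry the change (99.73rd percentile without it), although FKBP5 and ZBTB16 carried 28 of the net change of 49. Without both genes the percentile was 97.93. Among lists matched on loops within 2.5 Mb the percentile was 99.99. That matching was on the number of loops nearby and not on their change between the libraries. It therefore cannot decide on regional differences in detection, which stay open. At bins with gene ends the percentile was 100, for a summed change of 36. FKBP5 went from 0 to 16 partners there, since these bins leave out the T0 hub beside it. This count is thus open to a shift of loop ends, and no value without FKBP5 was computed. A shift of loop ends by a bin or so across gene boundaries may account for part of the pattern: with loops counted at genes widened by 10 kb the percentile was 95.9, below the bound set before that test was run, while the change in contacts at the same widened genes lay above it, at 99.32. An effect of progestin stays open and untested, since exposure and library coincide with 1 library per condition. More partners in T30 could also reflect enrichment by the antibody and not contact, which were not separated.

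Loops were shorter in T30. The lower minimum span of T0 would act the other way, and the T0 median at 20 kb or more was 210 kb; at q under 0.01 the T0 median was still 2.44 times that of T30. A difference in depth alone was taken to move all spans one way, whereas T30 had 8.4 loops per T0 loop at 20 to 50 kb and 0.367 at 500 to 1000 kb. That premise was not tested. The T30 to T0 ratio of expected contacts at identical bins was 0.360 under 100 kb and 0.553 at 200 kb or more. Depth could thus act unevenly by span, and the values do not set it aside. Another background model for each list could give the pattern, and the test did not decide: the ratio of expected contacts differed 1.54 times between long and short spans as it stands, and 1.07 times with 1 contact taken from each expectation, which level off near 1.05 in T30 at 1000 kb or more. Both forms were tried and neither was preferred, so depth, the model and progestin cannot be told apart.

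T30 loops lay somewhat more often in the 122 gene-dense windows of 5 Mb (46.93% against 43.17% in T0). Shorter loops could be the source, since within loops of 100 to 200 kb the difference was -2.54 percentage points, with T30 lower, and at 20 to 50 kb it was -20.32. Against that, at 200 to 500 kb T30 was higher by 3.91 points, and the value at 100 to 200 kb met neither bound set before the test (a difference under 2 points, or T30 higher by over 5), which leaves this open. At q under 0.01 the difference was 4.46 points, which lies between the same bounds for loops near the threshold. An effect of progestin was not tested.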

How the results depend on the processing

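No paired analysis was possible because each condition had 1 library. Of the main results under another setting, 148 stayed within the tolerance and 48 moved beyond it; of the named genes' changes, 123 stayed within it, 15 moved and 2 reversed. The tolerance was 1.5 times for a count and the 95% counting interval for other values, which for single genes is wide. Spans of at least 20 kb, gene ends, genes within 10 kb and expected contacts were chosen after the data were seen; the cause was not tested except where fewer loops or wider genes are the alternative itself. Motifs and scaling by coverage of the ends were not run. Sequencing depth is unknown, and a difference in depth was weighed only for the spans of loops. The number of lower calls followed the scaling.

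At q under 0.01, loops numbered 4284 in T0 and 5500 in T30 (1.28 per T0 loop), T30 had 3117 genes with a loop, 25.77% of T0 and 19.96% of T30 loops were shared, both ends lay in genes for 33.96% and 42.18%, and growth factor genes had 8 members in T0. With at least 10 contacts the median spans were 165 kb and 70 kb, and both ends lay in genes for 37.73% and 45.25%. With lists of equal length the ratio was 1 by construction, and 20.35% and 19.65% were shared. At spans of at least 20 kb the ratio was 1.48, the T0 median 210 kb, 24.09% of T0 loops were shared and 33.79% had both ends in genes.

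Shared loops were 8.59% of T0 and 6.34% of T30 with both anchors identical, and 36.37% and 27.43% within 10 kb. Calls of higher contacts numbered 5 with identical anchors, 7 with summed contacts, 6 with no scaling and 147 with expected contacts; lower calls numbered 123 with summed contacts and 43 with no scaling.

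Both ends lay in genes for 41.8% of T0 and 48.73% of T30 loops with genes widened by 2500 bp, 54.02% and 59.42% with all annotated genes, and 4.96% and 4.71% with either gene end. With either gene end, 2325 genes in T0 and 2649 in T30 had a loop, and members with a loop numbered 7 for progestin targets in T0, 5 for cell cycle and 3 for coregulator genes in T0, 8 and 7 for growth factor genes, and 1 for other tissues in T30. There the change in partners was -7 at GSE1 and -1 at NDUFAF6. At q under 0.01 it was 14 at VAV2, the only named gene that left the wide counting interval in a setting other than gene ends. Changes within that interval could still be large, as at KCNMA1 and FKBP5 with widened genes. With genes within 10 kb, T0 had 19 progestin targets and 9 housekeeping genes with a loop, and other tissues had 5 and 7. Over the settings the percentile of the progestin change ranged from 95 to 100, and that of housekeeping genes from 20.08 to 98.5. These come from 2000 random lists per setting. The 95, for genes within 10 kb, was 96.5 with 10000 lists, and 10 further draws gave 95.58 to 97 with 2000 lists and 95.99 to 96.51 with 10000.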

Other observations

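Loops of 1 list were also set against the most contacts that could have stayed unlisted in the other, taken from the 90th percentile of expected contacts at their span, a test chosen after the data were seen. Beyond that limit were 20 of 8014 loops of T30 and 0 of 4935 of T0 (exact binomial test, adjusted at 0.05, relative to the median ratio of shared loops). The split followed the scaling in part, with 6 of T30 and 2 of T0 by summed contacts, and 5 and 2 with no scaling. The 20 included loops within KCNMA1 (61 contacts, where at most 20 would have stayed unlisted), within MYOF, a membrane repair gene (67 and 26), within ZNF704 (54 and 23), and from 114035001 on chromosome 11 to ZBTB16 (33 and 14). The loop with the largest ratio to its limit, on chromosome 17 between 25920001 and 26590001, held no protein-coding gene at either end (47 and 8). It lies in a window of 5 Mb, from 25000001 to 30000000, where T0 listed 0 loops and T30 listed 49, so T0 lacked every loop there and not this one alone. The window from 40000001 to 45000000 on chromosome 8 likewise held 0 loops in T0 and 65 in T30. The limit takes for granted that loops at a place could be listed in the other library. That was not tested, so a loop beyond the limit need not be a difference of that loop.

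Some genes of the fixed lists had loops at the same or nearby bins in both libraries. GATA3 met a bin more than 1000 kb away in each, with 18 contacts in T0 (8045001 to 9195001) and 19 in T30 (8050001 to 9205001). FOXA1 met MIPOL1 with 11 and 20 contacts, from 37240001 to 37585001 in T0 and from 37245001 to 37590001 in T30. MYC met the bin at 127870001 on chromosome 8 with 14 and 25 contacts, between identical bins. TP63, a basal transcription factor, had 6 loops in T0 and 0 in T30, and PECAM1, an endothelial adhesion gene, had 5 and 1.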
